A study of Homo sapiens with 9 samples.

How the data were processed

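Total RNA of A549 cells after 5 days of culture was measured on 9 Affymetrix arrays, 3 for each of 3 conditions. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA by a 3' in vitro transcription protocol of Affymetrix. Such a protocol belongs to arrays that probe the 3' ends of transcripts, whereas the numeric identifiers here also name microRNA and other non-coding genes, as on whole-transcript arrays. How the 2 fit together is not given in the sources used here, so what part of a transcript an intensity reads is uncertain. The deposited values are intensities on a linear scale, 1 per probe set and array, that the authors made with MAS5, per the submitters' processing notes. Its version and settings and the array annotation the authors used are not given in the sources used here. The table held 53617 probe sets, with numeric identifiers, and each array's column was matched to its sample by accession. Groups and replicate numbers came from the sample titles. Per the series' design text each condition was collected 3 times, but nothing says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

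Probe sets were named from GEO's platform annotation, with symbols updated through gene identifiers in a RefSeq table. Of the probe sets, 16098 had 1 gene symbol, 0 had several and 37519 were not named here. The named ones stood for 14884 genes, and all 16098 matched by gene identifier. No coordinates were used.

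Attachment replicate 1 was left out of all main values, although the design fixed before the data were examined included it. Its median intensity was 15.8, against 23.3 to 24.1 on the other 8 arrays, and its highest rank correlation with another array was −0.00191. Of 86 neighbouring probe-set pairs with identical values on all 6 low-attachment arrays, 1 pair was identical on this array, against 86 on each of attachment replicates 2 and 3. A fit with all 9 arrays was run as an alternative.

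Values were taken as log2 of the intensity, with no pseudocount and no further normalization. The authors' values were assumed to be already scaled per array, though the settings of MAS5 are not given. Total intensity was 6810560 and 6658210 on attachment replicates 2 and 3, against 6384440 to 6569900 on the 6 low-attachment arrays. Mean intensities given in the text are the mean log2 values turned back to the linear scale. A probe set was kept where it was at or above the array's median on at least 3 of the 8 arrays (27942 probe sets, 11711 of them named). With 2 attachment arrays left, a probe set that reached the median only on those was dropped. One that reached it only on the 3 arrays of a low-attachment group was kept. Rises from below the median against attachment plates could thus be tested where the matching falls could not. For each of the 10916 genes left, the probe set with the highest mean stood for the gene, and 455 genes had more than 1. The 3 group means were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 5 residual degrees of freedom and 5.6 prior ones. Contrasts were two-sided, adjusted with Benjamini-Hochberg over genes, and called at an adjusted p under 0.05. A moderated F-test took all 3 groups together.

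The 28 gene lists were fixed before the data were examined: hypoxia, glycolysis, cholesterol, fatty acids, DNA replication, mitosis, ATF4 response, chaperones of the endoplasmic reticulum, heat shock, YAP and TAZ targets, actin and SRF targets, integrins, matrix, epithelial, mesenchymal, p53 targets, NRF2 targets, inflammatory, interferon, ERK output, lysosome, cell death, respiratory chain, lung, stem cell, and markers of fibroblasts, leukocytes and endothelial cells as other cell types. They were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, over 81 tests. The fibroblast list had 1 tested member and no test. Many members were not named or too dim. Of 25 hypoxia genes 15 were tested, of 26 replication genes 21, of 26 mitosis genes 22, of 22 p53 targets 11, of 21 actin genes 9 and of 12 heat shock genes 6. In no called list did the median, the mean and the test differ in sign.

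Genes were named by a rule fixed at the same time. It took, per comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 4 called members of each list with the largest change, fewer where room was short. For a list with no called member, the brightest one could be named. Genes called only with a block were named after their values were seen.

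Whether replicate numbers pair the samples was checked by the correlation of same-numbered arrays' deviations from their group means. For the low-attachment arrays without and with FP001 it was 0.483, 0.309 and 0.231 for numbers 1, 2 and 3, each above 0.1 and above the values with other numbers. The numbers were therefore taken to pair these 6 arrays, though with 3 arrays per group such a best match can arise by chance. The pairing comes from the data, not from the labels. For attachment replicates 2 and 3 it was −0.205 and 0.138 with low attachment and −0.256 and 0.00762 with FP001, so no pairing was seen. The deviations of only 2 arrays from their mean mirror each other, so this check cannot show that pairing is absent.

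The fits were tested on simulated data with the real genes' means and spreads, 10916 genes of which 200 changed. For low attachment against attachment, 67.5% of 1.5-fold, 97.6% of 2-fold and 100% of 4-fold changes were recovered. For FP001 against attachment the shares were 71.6%, 98.5% and 100%, and for FP001 against low attachment 81.5%, 99.1% and 100%. False calls made up 6.26%, 4.96% and 6.03% of calls in these comparisons. In these sets 200 genes changed and arrays varied independently, whereas 12 genes were called between FP001 and low attachment in the real data. There, without a block, TF (2.53-fold, limma adjusted p = 0.139) and KRT20 (2.14-fold, 0.364) missed the threshold. The shares recovered thus cannot show that no 2-fold change was missed. Over 20 simulated sets without change, 1 list was called in all, and a list shifted by 0.25 was called in 20 of 20. Genes varied independently in these sets, whereas the correlation estimated in the real data was 0.781 for the replication list and 0.806 for the mitosis list. The simulation thus cannot show how often lists are falsely called where members vary together.

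Alternatives set before the data were examined were quantile normalization, median centring, a pseudocount of 9.01 (the 25th percentile of all values), no filter, a filter at the 75th percentile, the mean of a gene's probe sets, no variance trend, array weights, only the groups compared, the replicate block, and each array left out. Added afterwards were all 9 arrays, the 6 low-attachment arrays with the block, and both low-attachment arrays numbered 1 left out, as well as simulated unchanged groups in which same-numbered low-attachment arrays correlated at 0.341, the mean of the values above. Figures were drawn in Python 3.11.15.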

Results

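A549 is an established human cell line from a lung adenocarcinoma that normally grows attached to plastic. The cells were kept for 5 days in 1 of 3 conditions, and the RNA of each sample was read on an expression array. The control condition was an ordinary plate on which cells attach, with normal medium. The other conditions were a low-attachment plate with normal medium and a low-attachment plate with medium holding 0.015% (w/v) of an additive labelled FP001. Each condition had 3 arrays. Attachment replicate 1 did not follow any other array (its highest rank correlation with another array was −0.00191) and was left out, so the values below rest on 2 attachment arrays and 3 arrays of each low-attachment group. On those 8 arrays the median intensity lay between 23.3 and 24.1, and rank correlations between arrays lay between 0.961 and 0.985. The small number of arrays limits the precision of every value. Errors of fold changes are standard errors (SE) from limma, and adjusted p-values are Benjamini-Hochberg values over the 10916 genes tested.

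The first comparison asked what changed when cells could no longer attach. On low-attachment plates in normal medium, the 8 genes with the largest rise included several of cell-surface or secreted proteins, and the 8 with the largest fall included the transcription factors EGR1, JUN and FOS beside matrix genes. CEACAM6 and CEACAM5, adhesion molecules of the carcinoembryonic antigen family, rose 7.18-fold (log2 fold change 2.84 ± 0.52, adjusted p = 0.00808) and 6.35-fold (2.67 ± 0.53, adjusted p = 0.0112). NOX1, a superoxide-producing oxidase, rose 6.04-fold (2.59 ± 0.22, adjusted p = 0.000188), and TPPP3, a microtubule-binding protein, rose 5.64-fold (2.50 ± 0.30, adjusted p = 0.00111). AGR3 and VSIG1 each rose 5.22-fold, and the secreted antibacterial enzyme LYZ and the protease inhibitor SLPI rose 4.78-fold and 4.35-fold. The transcription factor EGR1 fell 10.3-fold, from a mean intensity of 673.7 to 65.5 (log2 fold change −3.36 ± 0.11, adjusted p = 1.21e-07). The matrix proteins VCAN (versican) and FBN2 (fibrillin-2) fell 4.81-fold and 4.43-fold. JUN and FOS, which together form the AP-1 transcription factor, fell 3.81-fold and 3.47-fold, and DUSP1, a phosphatase that switches off MAP kinases, fell 4.01-fold. The microRNA gene MIR3189 fell 4.29-fold and the secreted protein gene IGFBP7 3.46-fold. Without attachment replicate 2 or 3 the log2 fold change was 3.57 or 2.12 for CEACAM6 and 3.12 or 1.87 for TPPP3, and without low-attachment replicate 1 it was 2.04 for CEACAM5. That array also read highest of its group for CEACAM6 (3342.7, against 903.1 and 1432.5), AGR3 (150.9, against 53.2 and 48.0) and LYZ (133.5, against 61.5 and 78.0). NOX1 read highest on low-attachment replicate 3. CEACAM6 and CEACAM5 missed the threshold without attachment replicate 3 (adjusted p = 0.083 and 0.108), and AGR3, at a mean intensity of 13.9 on the attachment plates and so under the array median, missed it without replicate 2 or 3 (0.073 and 0.16).

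**Figure D1:**
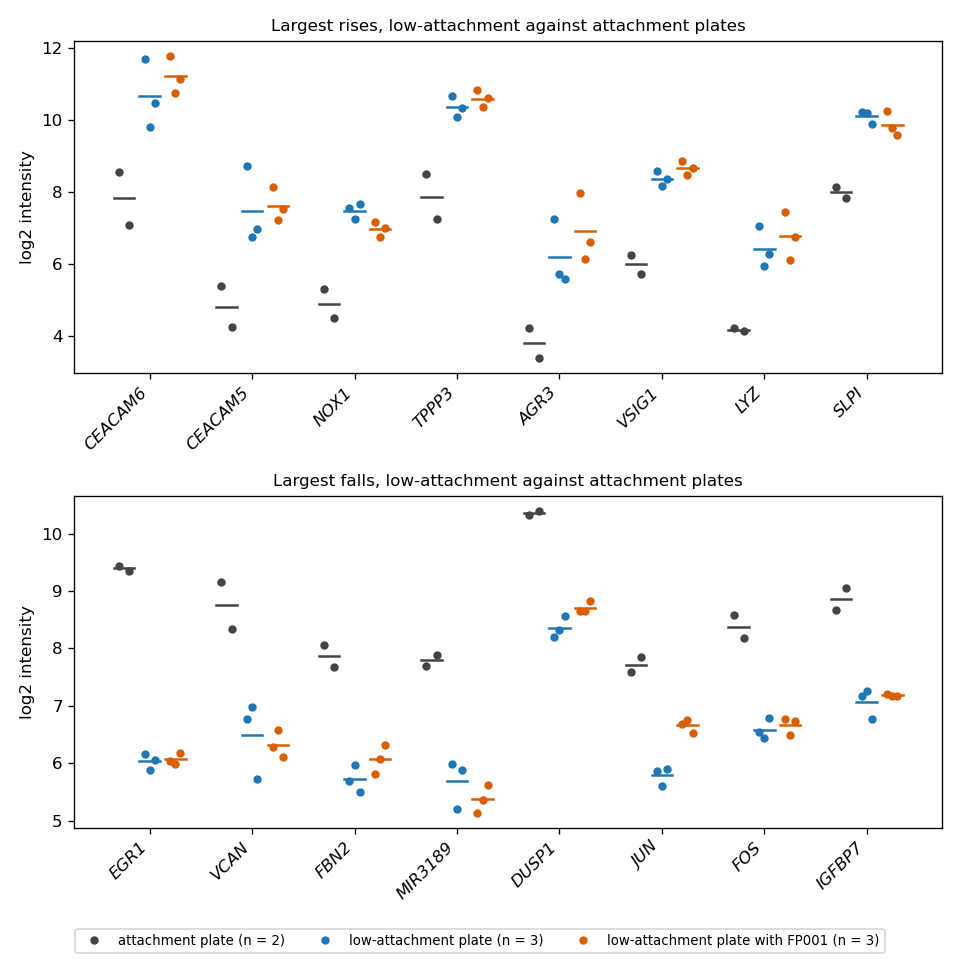
Log2 intensity of the 8 genes with the largest rise and the 8 with the largest fall between low-attachment and attachment plates, with 1 point per array and a line at each group's mean (attachment n = 2, low attachment n = 3, low attachment with FP001 n = 3). EGR1 had a mean intensity of 673.7 on attachment plates, 65.5 on low-attachment plates and 67.1 with FP001.

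In all, 1100 of the 10916 genes changed between low-attachment and attachment plates, 471 up and 629 down, and 66 of the rises and 65 of the falls were at least 2-fold. Quantile normalization turned the split to 612 up and 512 down (54.4% up, against 42.8%), so the balance of rises and falls rests on the scaling. With only 1 attachment array left, the count was 362 without attachment replicate 2 and 449 without attachment replicate 3, and it was 719 without low-attachment replicate 3.

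Several fixed gene lists were lower on low-attachment plates, by camera with a preset correlation of 0.01 over 81 list tests. Of 9 actin cytoskeleton and SRF target genes tested, 4 fell over all genes and 7 adjusted over the list alone (median log2 fold change −0.27, list adjusted p = 0.000257). These were TPM1, CNN2, VCL and CALD1, which encode proteins of actin filaments and their anchors, with log2 fold changes of −0.77 ± 0.13, −0.68 ± 0.08, −0.64 ± 0.10 and −0.51 ± 0.10. Of 11 p53 target genes, 7 fell (7 fell and 1 rose adjusted over the list alone), with a median of −0.47 (list adjusted p = 0.000711). Among them, the stress cytokine gene GDF15 fell 2.33-fold (adjusted p = 0.000596), SESN1 1.73-fold and the cell death gene BAX 1.58-fold. Of 6 cytosolic heat shock genes, 2 fell (5 adjusted over the list alone), HSPH1 by 1.93-fold and HSPB1 by 1.33-fold, with a list median of −0.30 (adjusted p = 0.000711). Of 22 mitosis genes, 2 fell (6 adjusted over the list alone), the kinases AURKA (1.71-fold) and TTK (1.45-fold), with a list median of −0.27 (adjusted p = 0.00027). With an estimated correlation none of these lists was called (adjusted p = 0.743 for mitosis and 0.691 for the other lists), and with fry, another list test, the mitosis list was not (0.252). Without attachment replicate 2, TPM1, CALD1, BAX, AURKA and TTK missed the threshold (adjusted p = 0.0644, 0.0849, 0.0731, 0.0713 and 0.0884), as did CALD1, AURKA and TTK without attachment replicate 3 (0.0576, 0.108 and 0.164) and TTK without low-attachment replicate 3 (0.054).

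Another 4 lists were called as lower in this comparison. Of 11 ATF4 and amino acid response genes, 5 fell (5 fell and 1 rose adjusted over the list alone; list median −0.28, adjusted p = 0.00618), among them the lipoprotein receptor VLDLR (2.00-fold), the serine synthesis enzyme PHGDH (1.78-fold) and the asparagine synthetase ASNS (1.52-fold). Of 12 fatty acid synthesis genes, 4 fell (7 adjusted over the list alone; list median −0.25, adjusted p = 0.00761), led by the desaturase SCD and by FASN, which fell 1.58-fold and 1.52-fold. Of 15 hypoxia response genes, 3 fell (4 fell and 1 rose adjusted over the list alone; list median −0.23, adjusted p = 0.0162), among them ADM and ANGPTL4, and without attachment replicate 2 the list was not called (adjusted p = 0.362). Of 17 ERK output genes, 2 rose and 3 fell, over all genes and adjusted over the list alone (list median −0.22, adjusted p = 0.0423), with EGR1 and FOS down and ETV4 up by 1.45-fold. The ERK list was lost with the replicate number as a block (adjusted p = 0.0988) and without attachment replicate 3 (0.0626), low-attachment replicate 1 (0.144), low-attachment replicate 2 (0.0622) or FP001 replicate 3 (0.0644). With an estimated correlation the adjusted p was 0.691 for each of these 4 lists, and with fry the ATF4 and hypoxia lists were not called (0.0723 and 0.163). Without attachment replicate 2, PHGDH, ASNS and FASN missed the threshold (adjusted p = 0.073, 0.146 and 0.0626), as did PHGDH and ANGPTL4 without attachment replicate 3 (0.0605 and 0.0616).

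No other list was called in this comparison, with adjusted p-values from 0.153 to 0.97. Members still changed one by one, and the counts in parentheses are adjusted over the list alone. Among 16 epithelial junction and keratin genes 3 rose and 2 fell (3 and 2), with KRT19 up 2.04-fold and the tight junction gene CLDN1 down 1.83-fold. Of 9 mesenchymal genes 1 rose and 1 fell (1 and 1), of 8 matrix genes 1 rose and 3 fell (1 and 3), and of 7 integrin and focal adhesion genes 1 rose and 1 fell (1 and 4). Of 12 YAP and TAZ targets 1 rose and 3 fell (1 and 3), of 11 inflammatory genes 2 rose and 3 fell (2 and 4), and of 9 interferon-stimulated genes 1 rose (2). The YAP and TAZ, integrin and matrix lists were fixed with 22, 22 and 26 genes, so much of each had no test. The complement gene CFB rose 2.29-fold and the chemokine gene CCL2 1.91-fold, while LIF fell 1.90-fold. Of 14 lysosome and autophagy genes 3 rose (5 rose and 1 fell), with the protease CTSD up 1.36-fold, and of 11 NRF2 targets 2 rose and 1 fell (2 and 2). Of 21 DNA replication genes 2 rose and 1 fell (2 and 3), with the cyclin gene CCNE2 up 1.90-fold. Of 7 endoplasmic reticulum chaperone genes 1 rose (1), of 11 lung epithelial markers 1 rose and 1 fell (1 and 1), and of 7 stem cell markers 1 fell (1). KRT19 missed the threshold without attachment replicate 3 (adjusted p = 0.13) and CCL2 without attachment replicate 2 (0.0841). No member of the glycolysis (8 tested), cholesterol synthesis (15), respiratory chain (8) and cell death (11) lists passed, in either count. The same held for 6 markers of leukocytes and 2 of endothelial cells. Of the fibroblast markers only LUM was tested (log2 fold change 0.29 ± 0.94, adjusted p = 0.872), so that list had no test.

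The second comparison set low-attachment plates with FP001 against attachment plates, so that plate and medium differed together. CEACAM6 rose 10.6-fold (log2 fold change 3.40 ± 0.52, adjusted p = 0.00203), the intestinal-type keratin KRT20 8.75-fold (3.13 ± 0.47, adjusted p = 0.00186) and AGR3 8.62-fold (3.11 ± 0.55, adjusted p = 0.00449). CEACAM5, TPPP3, VSIG1, LYZ and CD22, a lectin known from B lymphocytes, rose 7.02-fold, 6.62-fold, 6.41-fold, 6.07-fold and 4.69-fold. EGR1 fell 10.0-fold (−3.33 ± 0.11, adjusted p = 1.35e-07), MIR21 5.95-fold, VCAN 5.39-fold, MIR3189 5.36-fold and MIR590 4.50-fold. NNMT, which methylates nicotinamide, fell 4.47-fold, the lubricant glycoprotein gene PRG4 4.20-fold and BAAT, an enzyme of bile acid conjugation, 3.69-fold. Without attachment replicate 2 or 3 the log2 fold change was 4.13 or 2.67 for CEACAM6 and 3.35 or 2.11 for TPPP3. CEACAM5 missed the threshold without attachment replicate 3 (adjusted p = 0.0587), and PRG4 without attachment replicate 2 (0.0713). Probe sets named for microRNA genes were read like any other probe set here, which is not a measurement of the mature microRNA.

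In all, 2126 of the 10916 genes changed between FP001 and attachment plates, 882 up and 1244 down, and 72 of the rises and 134 of the falls were at least 2-fold. Quantile normalization turned the split to 1241 up and 968 down (56.2% up, against 41.5%). The count was 660 without attachment replicate 2, 1106 without attachment replicate 3, 1278 without FP001 replicate 1 and 1335 without FP001 replicate 2.

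Of 15 hypoxia-response genes, 8 fell with FP001 against attachment (10 adjusted over the list alone), with a list median of −0.43 (adjusted p = 0.00027). The largest falls were ANGPTL4 (1.97-fold), the vasodilator peptide gene ADM (1.88-fold), STC2 (1.81-fold) and the mitophagy receptor BNIP3L (1.68-fold). Of 6 heat shock genes 4 fell (5 adjusted over the list alone; list median −0.33, adjusted p = 0.00412), led by HSPH1 (1.79-fold), and of 9 actin and SRF genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; list median −0.34, adjusted p = 0.0185), led by TPM1 (1.73-fold) and CNN2 (1.68-fold). Of 11 p53 targets 7 fell (7 adjusted over the list alone; list median −0.41, adjusted p = 0.00761), led by SESN1 (1.63-fold), and of 11 ATF4 response genes 1 rose and 5 fell (1 and 6 adjusted over the list alone; list median −0.32, adjusted p = 0.0251), led by VLDLR (2.18-fold) and CTH (1.90-fold). With an estimated correlation the adjusted p was 0.691 for all 5 lists, and with fry the ATF4 list was not called (0.0771). The actin list was not called without attachment replicate 3 (adjusted p = 0.0911) or FP001 replicate 3 (0.0644), the p53 list without attachment replicate 2 (0.0682), and the ATF4 list without attachment replicate 2 (0.0896) or FP001 replicate 3 (0.0511).

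Of 21 DNA replication genes 3 rose with FP001 against attachment (3 adjusted over the list alone), among them CCNE2 by 2.38-fold and RRM2 by 2.03-fold, and the list was not called (adjusted p = 0.165). With the replicate number as a block, although no pairing of the attachment arrays by number was seen, it was called (6 rose and 10 adjusted over the list alone, median 0.18, adjusted p = 0.00249), and with an estimated correlation it was not (0.753 with the block, 0.876 without). The remaining lists had adjusted p-values from 0.153 to 0.951, and the counts in parentheses are again adjusted over the list alone. Of 11 NRF2 targets 3 rose (7 rose and 2 fell), led by OSGIN1 (1.75-fold), and of 16 epithelial genes 3 rose and 4 fell (3 and 5), with KRT19 up 2.93-fold and the desmosome protein DSP down 2.14-fold. Of 12 fatty acid genes 3 fell (4), of 8 glycolysis genes 1 fell (1), and of 17 ERK output genes 1 rose and 2 fell (2 and 2). Of 11 inflammatory genes 2 rose and 2 fell (3 and 3), with the complement gene C3 down 2.14-fold (log2 fold change −0.50 or −1.69 without attachment replicate 2 or 3), and of 9 interferon genes 2 rose and 1 fell (3 and 1). Of 14 lysosome genes 3 rose and 2 fell (3 and 2), of 12 YAP and TAZ targets 1 rose and 1 fell (2 and 3), and of 7 integrin genes 2 fell (1 rose and 2 fell). The integrin list was called as lower with fry (adjusted p = 0.0498), though not with camera (0.349) or with fry and the replicate block (0.0924). Of 8 matrix genes 1 fell (1), of 9 mesenchymal genes 1 rose and 1 fell (1 and 1), and of 7 chaperone genes 1 rose and 1 fell (1 and 1). Of 11 lung markers 2 rose and 1 fell (2 and 1), of 7 stem cell markers 1 fell (1), of 11 cell death genes 1 rose (1), and of 8 respiratory chain genes 1 rose (0). The macrophage marker CD68 was the 1 of 6 leukocyte markers that rose (2 adjusted over the list alone), by 1.67-fold. Without attachment replicate 2, RRM2, DSP and CD68 missed the threshold (adjusted p = 0.0543, 0.0965 and 0.0645), as did CD68 without attachment replicate 3 (0.0922). No mitosis (22), cholesterol (15) or endothelial (2) gene passed in either count, and LUM had a log2 fold change of 1.57 ± 0.94 (adjusted p = 0.256).

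**Figure D2:**
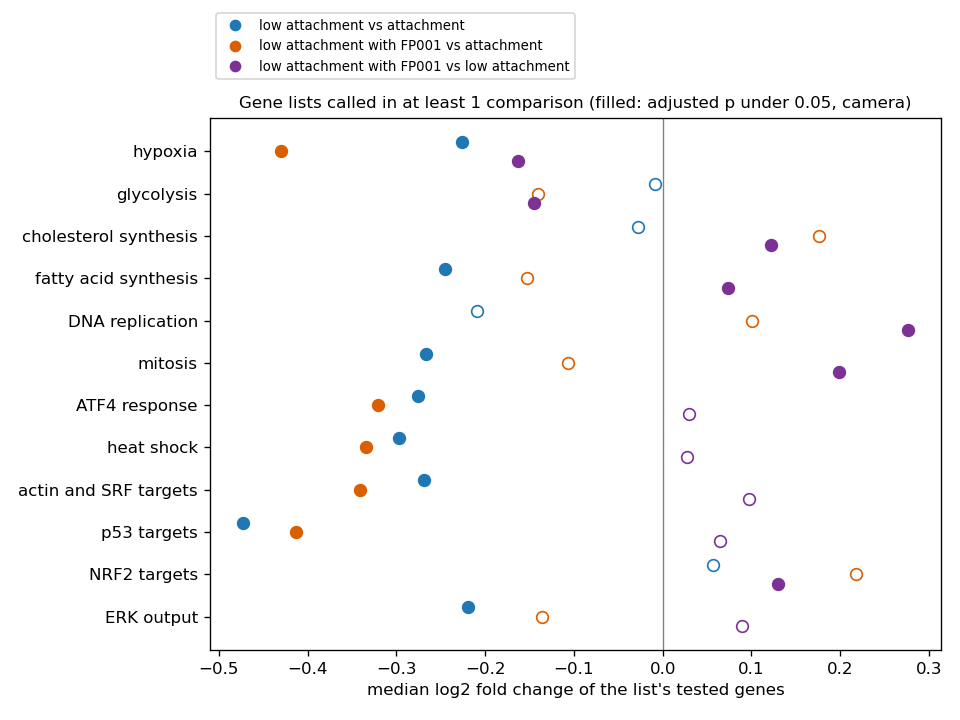
Median log2 fold change of the tested genes of each list called in at least 1 comparison, with 1 point per comparison, filled where camera with the preset correlation gave an adjusted p under 0.05. The DNA replication list lies at 0.28 and the hypoxia list at −0.16 for FP001 against normal medium on low-attachment plates.

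Both comparisons used the same 2 attachment arrays. Across genes their log2 fold changes correlated at 0.878, where unchanged groups of independent arrays simulated against shared attachment arrays gave 0.601, and the covariance was 0.0997 against 0.0114 simulated. Same-numbered low-attachment arrays varied together, and a simulation with that pairing, added after the data were seen, gave 0.736 and 0.0139. Genes are not independent replicates, so no p-value is given. The sign was the same for 83.4% of genes, against 70.5% simulated and 76.3% with the pairing. Of the calls, 362 genes rose in both comparisons and 545 fell in both, where independent lists of those sizes would share 38.1 and 71.7, and 0 genes were called in opposite directions. With 2 attachment arrays, a separate pair of controls for each comparison could not be formed, and the share of this excess that comes from the common arrays was not measured.

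The comparison of FP001 with normal medium on low-attachment plates asked what the additive changed there. JUN rose 1.82-fold with FP001 (log2 fold change 0.87 ± 0.11, adjusted p = 0.0212) and GDF15 1.70-fold (0.77 ± 0.12, adjusted p = 0.0455), and both had fallen on low-attachment plates in normal medium. That fall and this rise use the same 3 low-attachment arrays in normal medium, so chance low values there would favour both. The complement gene C5 fell 1.80-fold (−0.85 ± 0.11, adjusted p = 0.0212), the splicing-related gene LENG8 1.64-fold, the laminin receptor BCAM 1.63-fold (−0.70 ± 0.09, adjusted p = 0.0203) and the hypoxia-list gene BNIP3L 1.58-fold (−0.66 ± 0.08, adjusted p = 0.0198). The anticoagulant gene PROS1 and the pseudogene AADACP1 each fell 1.57-fold, and BCL9, a Wnt pathway co-activator, and LOC729737 each 1.44-fold. The probe sets of LOC729737 went opposite ways between low-attachment and attachment plates. SNAR-H and SNAR-B1 rose 1.95-fold and 1.66-fold, but these small RNA genes have near-identical copies, so which copy changed is uncertain. All 12 missed the threshold without FP001 replicate 1, 2 or 3 (adjusted p from 0.0609 to 0.137, from 0.098 to 0.233 and from 0.0767 to 0.138). Without low-attachment replicate 2 only SNAR-H passed (the others from 0.0517 to 0.14), and without low-attachment replicate 3 only SNAR-B1 (from 0.0508 to 0.209). GDF15, LENG8, BCL9 and LOC729737 also missed it without low-attachment replicate 1 (0.0935, 0.0935, 0.0935 and 0.0839), as did C5 (0.0504), and these 4 and AADACP1 without attachment replicate 2 (from 0.0507 to 0.0714) or 3 (from 0.0508 to 0.0721).

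**Figure D3:**
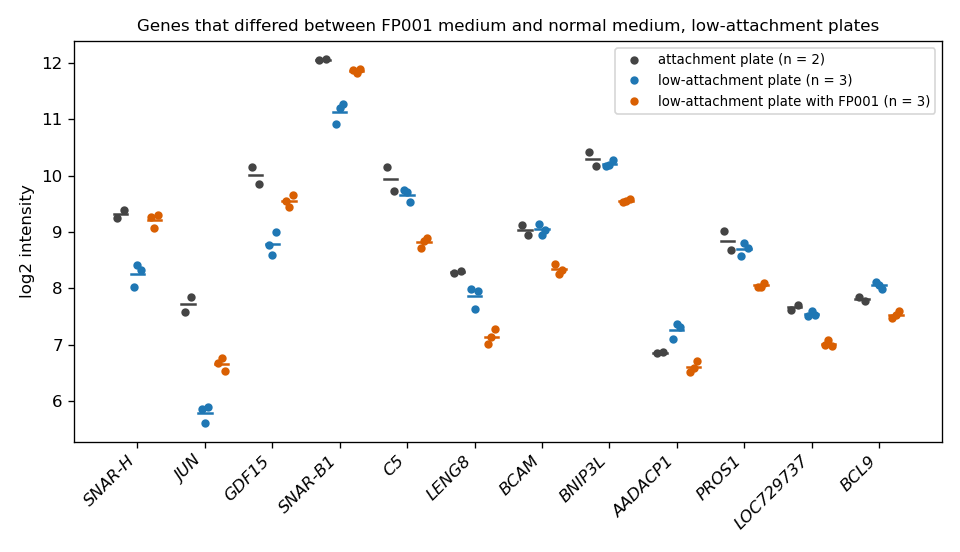
Log2 intensity of the 12 genes that differed between FP001 and normal medium on low-attachment plates, with 1 point per array and a line at each group's mean (attachment n = 2, low attachment n = 3, low attachment with FP001 n = 3). JUN had a mean intensity of 55.3 in normal medium, 100.9 with FP001 and 210.7 on attachment plates.

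In limma 12 of the 10916 genes changed between FP001 and normal medium, 4 up and 8 down and 0 of them by 2-fold, and 1265 had an unadjusted p under 0.05. Some estimated changes of over 2-fold, such as that of TF (2.53-fold, adjusted p = 0.139), missed the threshold. Array numbers were taken to pair the low-attachment arrays, a pairing that the labels do not give. With the replicate number as a block 142 genes changed, 50 up and 92 down, all 12 among them. The count without a block was 0 without FP001 replicate 1, 2 or 3, 1 without low-attachment replicate 2 or 3, and 9 without low-attachment replicate 1. Quantile normalization gave 9 genes, 44.4% of them up against 33.3%. In the 6 low-attachment arrays alone with the block, a fit added after the data were seen, 478 genes changed, 183 up and 295 down.

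Genes of the blocked fit are named here after their values were seen, from the 8 largest rises and 8 largest falls that went one way in all 3 pairs. With the replicate block, the iron carrier gene TF fell 2.53-fold with FP001 (log2 fold change −1.34 ± 0.13, adjusted p = 0.0015), TXNIP, an inhibitor of thioredoxin, 2.43-fold (−1.28 ± 0.21, adjusted p = 0.0161), the succinate receptor SUCNR1 2.35-fold and C3 2.19-fold (−1.13 ± 0.18, adjusted p = 0.015). The long non-coding RNA gene LINC01133 rose 2.43-fold (1.28 ± 0.18, adjusted p = 0.00643), KRT20 2.14-fold (1.10 ± 0.15, adjusted p = 0.00647), KRT80 1.93-fold and the annexin gene ANXA3 1.90-fold. The standard errors here are those of the blocked fit. The others of these 16 were the rises of MIR130B (2.05-fold), SNAR-H, JUN and CD22 and the falls of MIR27B, PMS2P9, MIR590 and MIR21. Without the block none of the 8 described first passed (TF 0.139, KRT20 0.364, KRT80 0.0578 as adjusted p).

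By camera with the preset correlation 7 lists were called between FP001 and normal medium on low-attachment plates, although few members passed singly, and with fry none of the 7 was called. All 21 DNA replication genes lay above 0 (median log2 fold change 0.28, list adjusted p = 2.89e-08), as did all 22 mitosis genes (median 0.20, adjusted p = 9.85e-06), with 0 called singly over all genes or adjusted over the list alone. The mitosis list had been called as lower on low-attachment plates in normal medium. That fall and this rise use the same 3 low-attachment arrays in normal medium, so chance low values there would favour both. PCNA, the replication clamp and the brightest of its list, had a log2 fold change of 0.31 ± 0.11 (adjusted p = 0.317) and the topoisomerase TOP2A of 0.15 ± 0.13 (0.709). With the replicate block 1 replication gene and 0 mitosis genes rose in the 8 arrays (15 and 9 adjusted over the list alone), and 9 and 4 in the 6 low-attachment arrays alone (19 and 13). Of 15 hypoxia genes 2 lay above 0 and 1, BNIP3L, fell (2 adjusted over the list alone; median −0.16, adjusted p = 0.000759), and of 8 glycolytic enzymes 1 lay above 0 and 0 passed (3 fell adjusted over the list alone; median −0.14, adjusted p = 0.00761). With the block 2 hypoxia genes and 1 glycolysis gene fell in the 8 arrays (2 and 3 adjusted over the list alone), and 3 and 2 in the 6 arrays (4 and 3). With an estimated correlation the adjusted p was 0.691 for these 4 lists, and with fry it was 0.243 for replication, 0.378 for mitosis, 0.189 for hypoxia and 0.15 for glycolysis.

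Smaller shifts upward were called for 11 NRF2 targets (median 0.13, adjusted p = 0.00761), 15 cholesterol synthesis genes (0.12, adjusted p = 0.0104) and 12 fatty acid genes (0.07, adjusted p = 0.0345). Without the block none of their members passed over all genes, and 0, 0 and 2 rose adjusted over the list alone. With the block 0, 2 and 0 rose in the 8 arrays (3, 3 and 2 adjusted over the list alone), and 2, 3 and 2 in the 6 low-attachment arrays (6, 3 and 2). With an estimated correlation the adjusted p was 0.691, 0.743 and 0.691, and with fry 0.189, 0.503 and 0.15. The fatty acid shift was absent from the pair of arrays numbered 1 (median 0.0127 with 6 of 12 above 0, median of all genes 0.0134) and rested on pairs 2 and 3 (0.131 and 0.17). The cholesterol list was not called without low-attachment replicate 2 (adjusted p = 0.122), low-attachment replicate 3 (0.152) or FP001 replicate 1 (0.511). The fatty acid list was not called without low-attachment replicate 2 (0.0816), low-attachment replicate 3 (0.158) or FP001 replicate 3 (0.233), and the NRF2 list without low-attachment replicate 1 (0.144) or FP001 replicate 3 (0.0644). The other lists had adjusted p-values from 0.0878 to 0.985. Of their members, GDF15 rose in the p53 list without the block (1 adjusted over the list alone). Adjusted over the list alone, 3 YAP and TAZ targets, 1 epithelial, 1 matrix and 1 respiratory chain gene rose, 2 inflammatory genes rose and 2 fell, and 2 interferon genes and 1 chaperone gene fell. No actin, heat shock, ATF4, ERK, integrin, mesenchymal, lysosome, cell death, lung, stem cell, leukocyte or endothelial gene passed in either count without the block, and LUM had a log2 fold change of 1.29 ± 0.84 (adjusted p = 0.595). In the 6 low-attachment arrays with the replicate block, LUM, the 1 fibroblast marker tested, rose with FP001 (1.29 ± 0.13, adjusted p = 3e-04).

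The block changed the counts of these other lists too. In the 8 arrays with the block 1 p53, 1 matrix, 2 epithelial and 2 inflammatory genes rose over all genes, and 1 epithelial, 2 inflammatory and 1 chaperone gene fell. In the 6 low-attachment arrays 3 YAP and TAZ targets, 2 matrix, 2 epithelial, 1 p53, 2 inflammatory, 1 ERK, 2 respiratory chain and 1 leukocyte gene rose. In the same fit 1 YAP and TAZ target, 2 matrix, 4 epithelial, 1 p53, 2 inflammatory, 1 interferon, 1 ERK and 1 chaperone gene fell. None of these lists was called in the 6 arrays with the block (adjusted p from 0.0668 to 0.931).

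**Figure D4:**
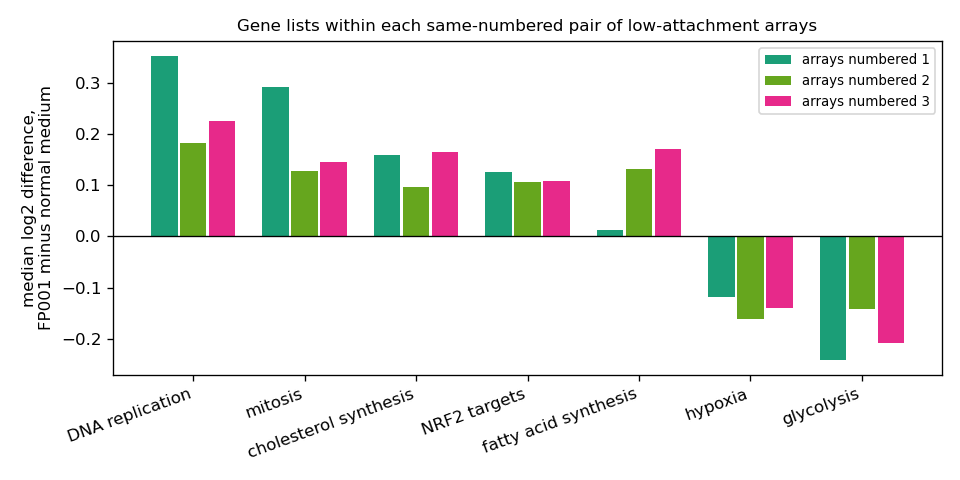
Median log2 difference between FP001 and normal medium for each list called in that comparison, as 1 bar for each same-numbered pair of low-attachment arrays (n = 1 pair per bar). The DNA replication list lies at 0.351, 0.183 and 0.226 and the hypoxia list at −0.117, −0.161 and −0.140.

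A single test over the 3 groups, the moderated F-test of limma, called 1526 of 10916 genes. It called 412 without attachment replicate 2, 627 without attachment replicate 3 and 962 without FP001 replicate 2. There was no attachment group with FP001, so whether the additive acts differently on the 2 kinds of plate was not tested.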

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

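Tests of attachment replicate 1 and of the immediate early genes were chosen after the result was seen. Those of the lists with FP001 were chosen after the lists were called but before their own values were seen, and the splits of the arrays before. Probe sets with no gene name here were kept out of the report's comparisons, and they too carried differences. Of 16231 such probe sets passing the same filter, 317 changed between low-attachment and attachment plates (134 up, 183 down), 1798 between FP001 and attachment (505 up, 1293 down) and 1 between FP001 and normal medium on low-attachment plates. The shares were 1.95%, 11.1% and 0.00616%, against 10.1%, 19.5% and 0.11% of named genes. Unnamed probe sets were fitted and adjusted apart and each was counted, while a named gene was counted by 1 probe set. The thresholds thus differ, and the shares can be set side by side only roughly.

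Attachment replicate 1 shared no pattern with any other array. If it were another human sample with its rows in place, it should correlate with the rest, and its highest rank correlation was −0.00191, which argues against that. Values attached to the wrong rows would break up neighbouring probe sets that are otherwise identical, and 1.16% of such pairs were identical on this array, against 100% on the other attachment arrays. An array like the others whose rows were only put in another order would keep its distribution, but the median intensity was 15.8, against 23.3 to 24.1 on the other 8 arrays, which argues against that. Values of some other kind or sample attached to the wrong rows are a possible explanation left standing, though any values unrelated to these probe sets would give such pairs. The original array file was not used here, so what the column holds stays open.

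With FP001 on low-attachment plates, the replication and mitosis lists were higher and the hypoxia list lower. The direction was not confined to 1 numbered pair of arrays, since all 9 list-by-pair medians went the same way as the groups. The lists had been called on these same arrays, which favours such agreement. The pair numbered 1 had the largest medians for replication (0.351, against 0.183 and 0.226) and mitosis (0.291, against 0.127 and 0.145). Array-wide scaling does not account for the replication list's change, because 104% of its median change was left after quantile normalization. That share was not computed for the mitosis and hypoxia lists, though all 20 list calls of the report were kept under quantile normalization. The replication, mitosis and hypoxia lists were called with a preset correlation only, and their calls ended with an estimated one and with fry, so chance co-movement of their members stays open. A difference in the cells' growth state or oxygen supply between media is a hypothesis that stays untested here.

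Several immediate early genes were lower on both kinds of low-attachment culture, and others were not. Of 15 tested, 8 fell and 1 rose against attachment plates in each medium, and of 12 delayed ERK output genes 1 fell and 2 rose in normal medium and 0 fell and 1 rose with FP001. A rapid response of attached cells at collection may raise the first kind and spare the second. The difference of medians was −0.383 in normal medium (two-sided permutation p = 0.0546, adjusted over 3 comparisons 0.0882) and −0.494 with FP001 (0.0588, adjusted 0.0882). Neither passes, and the test decides nothing in any case. The immediate early set was drawn up after EGR1, FOS, JUN and DUSP1 were seen among the largest falls and contains them, so the direction was largely fixed beforehand, and both comparisons share the same 2 attachment arrays. A rapid response and a lasting change cannot be told apart, as no time course was measured.

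Other splits of the arrays were counted to ask whether arbitrary groups give as many genes. For the F-test, 1 of 100 splits of the 8 arrays into 2, 3 and 3, the real one, gave 1526 genes or more, and the highest of the others gave 1161, so chance can be excluded only as an arbitrary grouping of these arrays. The next 2 splits, with 1161 and 592 genes, also kept both attachment arrays together. The splits took no account of the numbered pairs, and a chance difference between cultures stays open, since nothing says that the replicates were separate cultures. For FP001 against low attachment the real split gave 12 genes and the highest of the other 9 splits 0. With 10 splits in all, 1 of them the real one, a share under 0.05 cannot be reached. The real split parts all 3 numbered pairs, and the 3 others that do so gave 0 genes, with and without the replicate block, while the real one gave 142 with it. With so few such splits a share under 0.05 cannot be reached there either, and the pairing was itself taken from these arrays.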

How the results depend on the processing

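All alternatives were chosen before the data were examined except the fits with all 9 arrays, with the 6 low-attachment arrays and the replicate block, and without both low-attachment arrays numbered 1. An alternative set at that time, probe sets without certain suffixes, was not run because the identifiers carry none. Under quantile normalization, median centring, a pseudocount, no filter, a stricter filter and the mean of a gene's probe sets, every count of changed genes and the F-test count stayed within 1.5 times its value. Neither scaling moved the median of all genes by over 0.1. The ERK list lost its call under the stricter filter, the mean of probe sets and only the groups compared, the fatty acid list (FP001 against low attachment) under the mean of probe sets, and the ATF4, actin and p53 lists (FP001 against attachment) under the stricter filter. The number of genes changed between FP001 and normal medium was 0 without the variance trend and 35 with array weights, and the cause was not tested. It was 142 with the replicate block and 478 in the 6 low-attachment arrays with the replicate block. The second fit also left out the attachment arrays and filtered probe sets on the 6 arrays, so its higher count cannot be put down to the block alone. Both blocked fits had fewer residual degrees of freedom than the 5 of the main fit, so each gene's own spread is less well known in them. The block changed other calls for 2 lists only, the ERK list (low attachment) and the replication list (FP001 against attachment), and left the counts of the other comparisons and the F-test within 1.5 times. Leaving out 1 array gave 362 to 1301 genes changed between low-attachment and attachment plates, 660 to 2305 genes changed between FP001 and attachment plates, 0 to 11 for FP001 against low attachment and 412 to 1552 for the F-test. Where 1 attachment array was left, it was assumed to vary like the other groups. The counts against attachment and of the F-test moved both ways and that of FP001 against low attachment only down, and the cause was not tested. Of the 180 gene results named by the rule or the blocked fit, 14 were called only with the replicate block, 80 and 71 lost their call without attachment replicate 2 and 3, 22 to 38 without each other array, and 30 without the variance trend. Without both low-attachment arrays numbered 1, 13 of the 180 lost their call and 3 gained one. The correlation of the fold changes was 0.853 to 0.8991 with 1 array left out, 0.8641 with the replicate block, 0.8591 without both low-attachment arrays numbered 1 and 0.983 with all 9 arrays. The number of gene lists called, 20, became 0 with an estimated correlation, 10 with fry (9 of the 20 among them, none for FP001 against low attachment) and 1 with all 9 arrays. The 1 list called with fry only was the integrin list, lower with FP001 than on attachment plates. For each replicate left out the number of lists called was 15 to 21.

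Keeping attachment replicate 1 ends most results. With all 9 arrays in limma, 0 genes were called in each comparison and in the F-test (198, 330, 11 and 171 at an unadjusted p under 0.05, in the order of the report), and the median of all genes moved to 0.697 and 0.693 in the comparisons with attachment. A likely cause is that this array correlates with no other yet enters both comparisons with attachment, whose fold changes then correlate at 0.983. Of the 180 gene results named, 59 changed sign, as did 5 of the 20 list results, and no result changed sign under any other alternative. With all 9 arrays, list medians turned to fatty acid 0.87, heat shock 1.71 and actin 0.84 for low attachment against attachment, and to heat shock 1.67 and actin 1.07 with FP001 against attachment. For low attachment against attachment, log2 fold changes turned to ADM 0.67, ANGPTL4 0.24, SCD 0.59, ACLY 2.94, PCNA 0.94, AURKA 0.72, VLDLR 0.55, CTH 0.76, HSPH1 1.69, HSPB1 1.52, FOXF2 0.12 and CRIM1 0.72. In the same comparison they turned to CNN2 1.29, VCL 2.34, CALD1 0.33, ZYX 0.60, LOXL2 0.34, THBS1 1.45, TIMP2 0.48, CLDN1 0.71, KRT7 1.38, FSTL1 0.33, BAX 0.64 and RRM2B 0.81. Also turned were FOXA1 −0.92 and THY1 0.80. With FP001 against attachment they turned to BAAT 0.26, ANGPTL4 0.0776, ADM 0.58, BNIP3L 1.23, LDHA 1.30, SCD 0.80, ACLY 2.98, VLDLR 0.43, CTH 0.51, XBP1 0.28, HSPH1 1.80 and HSPB1 1.58. Further ones with FP001 were BAG3 1.66, HSPA1B 1.68, FOXF2 0.0908, CNN2 1.22, CALD1 0.36, VCL 2.51, LPXN 0.11, ZYX 0.54, LOXL2 0.18, DSP 0.13, CLDN1 0.79 and FSTL1 0.53. The rest with FP001 were BAX 0.69, RRM2B 0.85, CCNG1 1.54, C3 0.55, CCL2 −0.0762, IRF9 0.84, GABARAPL1 1.09, FOXA1 −1.02 and THY1 0.74.

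Arrays do not give a depth. Genes near the array median of about 23.3 to 24.1 are closest to background, and of the genes whose folds the report gives, AGR3 and LYZ (13.9 and 18.0 on attachment plates), PRG4 and MIR590 (20.3 and 10.1 with FP001) and SUCNR1 (with FP001) lay below it in a group compared, so their folds are uncertain. KRT20, CD22, CEACAM5 and NOX1 lay little above it on attachment plates (26.6, 27.3, 28.1 and 29.7), so their large rises are uncertain in size too. On attachment replicate 3 alone KRT20, CEACAM5 and NOX1 read below it (22.1, 18.9 and 22.5).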

Other observations

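All groupings in this part were chosen after the data were seen, and 168 families of genes that share the letters of their symbol were screened with camera in 3 comparisons. With FP001 against normal medium on low-attachment plates, the 25 keratin genes had a median log2 fold change of 0.23 (19 above 0, 0 called singly, adjusted p = 0.00049), and against attachment plates 6 of them rose and 0 fell (median 0.22, adjusted p = 0.0253). The 8 SNAR genes, small non-coding RNAs, were as a family higher with FP001 than without (median 0.54, 7 above 0, adjusted p = 1.4e-08, 2 rose) and lower on low-attachment than on attachment plates in normal medium (median −0.51, adjusted p = 0.025, 4 fell). Their copies are near-identical, so they are not independent measurements. Both SNAR values also use the same 3 low-attachment arrays in normal medium, so chance low values there would favour both. With an estimated correlation neither family was called (adjusted p = 0.873 for each of these values).

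Some other families of the screen were called as lower in at least 1 comparison with attachment plates, and with an estimated correlation none of them was called (adjusted p = 0.873 for each). Of 10 PRPF genes, which encode splicing factors, 5 fell in normal medium (median −0.38, adjusted p = 0.000955) and 4 with FP001 (−0.34, adjusted p = 0.00789), and of 9 SRSF splicing factor genes 4 fell with FP001 (−0.37, adjusted p = 0.032), while in normal medium that family was not called (adjusted p = 0.117). Nucleoporin genes (NUP, 22 tested) had a median of −0.30 in normal medium (2 fell, adjusted p = 0.00391) and −0.29 with FP001 (4 fell, adjusted p = 0.0211). Of 354 zinc finger genes (ZNF), 79 fell and 4 rose with FP001 against attachment (median −0.14, adjusted p = 0.000955), while in normal medium that family was not called (28 fell and 3 rose, median −0.07, adjusted p = 0.0567). All these medians kept their sign under quantile normalization and median centring, the ZNF one with FP001 shrinking to −0.0788.

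Several genes of plasma proteins that the liver secretes were among the strongest falls with FP001 in the 6 low-attachment arrays with the replicate block, such as the fibrinogen chains FGA (log2 fold change −0.74, adjusted p = 2.24e-05), FGB (−0.63, adjusted p = 6.15e-05) and FGG (−0.94, adjusted p = 2.24e-05). Without the block their adjusted p was 0.0928, 0.427 and 0.145. In normal medium some genes of this kind had risen against attachment plates, among them CP by 1.21 ± 0.17 and APOH by 1.30 ± 0.24 on the log2 scale. A hypothesis was that plasma protein genes shift as a group. Over all 27 tested of 49 listed, the median log2 fold change with FP001 was −0.293, with 20 below 0. Of the 27, 2 were called without the block and 13 in the 6 arrays with it, but this holds the 12 genes that prompted the hypothesis (median −0.794), all 12 of them called with the block. The 15 others had a median of −0.0146, with 8 below 0 and 1 called with the block. Removing the members with the strongest falls largely fixes such a remainder beforehand, so it decides nothing, and whether the group shifts stays open.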
